A study of Mus musculus with 2 samples.

How the data were processed

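Single-cell chromatin accessibility (Chromium Single Cell ATAC) was measured in 2 libraries of mouse cardiac fibroblasts, 1 transduced with Mef2c, Gata4 and Tbx5 retroviruses (MGT) and 1 with LacZ, and groups were taken from the sample titles. FastQC, Cell Ranger and Cell Ranger ATAC 1.1.0 and the build mm10 were used per the submitters' processing notes, which give no role or order for them. The authors deposited 1 table of peaks by barcodes per library, in which every value is 0 or 1, so the deposited values are detection calls and not counts. The peak caller, the filter that chose the barcodes and the step that made the values 0 or 1 are not given in the sources used here. Both tables list the same 140954 peaks in the same order, with a median width of 310 bp, so both libraries were scored on 1 shared set. Whether that set came from 1 joint call or from merged calls is not given. All deposited barcodes were used.

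The design had assumed counts. Since the values are calls, no count model was fitted: a peak's level is its share of barcodes, a gene locus is the sum of its detections, and the interval printed for a locus is that of the share of barcodes with at least 1 of its peaks. Detections were scaled to 1000000 detections in peaks per library, and log2 ratios used a pseudocount of 0.5. Peaks and genes needed at least 100 detections over both libraries. With 8559 and 10838 barcodes, a peak seen in 0 cells allows a share of up to 0.0350% in LacZ and 0.0277% in MGT (3 cells of the total). A call of 0 or 1 saturates in a cell with many fragments, which lowers ratios at the most accessible peaks. Depth differed little, with quartiles of 2489 and 4902 detected peaks per barcode in LacZ and 2401 and 5092 in MGT.

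Genes came from a RefSeq gene table of GRCm38.p6, the assembly known as mm10, with 21887 protein-coding genes of unique symbol, of which 17050 had a peak. A peak lay within 1 kb of the lower coordinate of 40.1% of genes, which may be either end of transcription, against 17.0% of positions 50 kb away. The table gives no strand, exons or sequence, so a gene locus was its span with 2 kb at both ends, and peaks within 1 kb of either gene end (18496 peaks) stood in for promoter peaks. Distal peaks had no gene end within 1 kb and were described by the nearest gene end. Exons of the delivered genes and sequence motifs (23 planned families) were not analysed here. All 418 symbols of the gene lists matched a gene, 1 of them by a synonym, and 16 had no peak. The 3 delivered genes stayed out of every list.

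With 1 library per group no test was run. Each list's median log2 ratio was placed among 10000 random lists of the same size matched in 20 bins of accessibility, as a description of these libraries, and a list stands apart under percentile 2.5 or over 97.5. Counts of peaks are counts by size of ratio. To show what counting error alone gives, 100 unchanged pairs were drawn from the peaks' pooled detections. Genes named are the 3 delivered genes, the 10 loci with the highest and the 10 with the lowest ratio among protein-coding genes with at least 500 detections (delivered genes left out), the 2 highest and 2 lowest members of each list, and the 5 most gained and 5 most lost distal peaks with at least 500 cells. Of the list members this rule names, 1 is not reported here. Within the delivered spans, peaks at least 2-fold higher in MGT were grouped by that ratio after it was seen, and of the 21 such peaks 20 have 100 cells.

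For clusters, peaks in at least 1.0% of cells outside the delivered loci and chromosome Y (95191 peaks) were weighted by TF-IDF and reduced to 30 components by singular value decomposition. Components with a correlation of 0.5 or more with log depth were left out, and 15 nearest neighbours were clustered by Leiden at resolution 0.6. No doublet caller was run, since those at hand model counts of RNA, and doublets were not removed. In the closing section, clusters were also made from odd or from even autosomes alone and each peak measured with the clusters of the other set.

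The ratio and list steps were tested on simulated libraries in which 200 of 140954 peaks were changed by known folds. Median estimated log2 ratios were 1.98 at 4-fold, 1.02 at 2-fold, 0.56 at 1.5-fold, -1.05 at 0.5-fold and -1.99 at 0.25-fold. Of 200 unchanged random lists, 4.50% fell outside percentiles 2.5 to 97.5. Alternatives changed the scaling, the barcodes kept, the depth per cell, the chromosomes, the minimum and the peaks that make a locus, and for clusters the resolution, the depth and the libraries clustered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.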

Results

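Chromatin accessibility was measured in single mouse cardiac fibroblasts, the matrix-producing cells of the heart, on day 3 of direct cardiac reprogramming, in which fibroblasts are pushed toward a cardiomyocyte-like state by adding transcription factors. Cells from CD1 mice at postnatal day 3 had received retroviruses carrying Mef2c, Gata4 and Tbx5 (MGT), or the bacterial reporter LacZ as a mock. There was 1 library per group, so no test between groups was possible, and intervals are exact 95% binomial (Clopper-Pearson) intervals that cover counting error only. The LacZ library held 8559 barcodes and the MGT library 10838, over the same 140954 peaks. Each value is a call of a peak as detected or not in a barcode. The LacZ library held 33249045 detections and the MGT library 43081002, with medians of 3591 and 3658 detected peaks per barcode. Levels are given as the share of barcodes with the peak, or as detections per 1000000 detections in peaks, and ratios are MGT over LacZ.

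The first comparison asked whether the loci of the 3 delivered factors set the libraries apart as their labels say. Short peaks within Mef2c, Gata4 and Tbx5 were far more often detected in MGT cells. Of the 58 peaks within the 3 gene spans, 21 were at least 2-fold higher in MGT, with a median width of 147 bp and a median log2 ratio of 3.42. The other 37 peaks, all less than 2-fold higher by this grouping, had a median width of 313 bp and a median log2 ratio of -0.03. That ratio was -0.04 for the 20 of Mef2c, -0.04 for the 13 of Gata4 and 0.31 for the 4 of Tbx5, which reached 0.82. Median widths of the higher against the other peaks were 165 and 289 bp in Mef2c and 152 and 328 bp in Gata4. In Tbx5 the order was reversed, at 138 and 114 bp. At least 1 of the 21 peaks was detected in 38.2% of MGT cells (37.3% to 39.1%) and in 8.37% of LacZ cells (7.79% to 8.97%).

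Mef2c, a MADS-box transcription factor, lies on chromosome 13 at 83504017 to 83667079 in mm10, and 7 of its 27 peaks were at least 2-fold higher in MGT. The highest ratio, a log2 value of 4.72, was at 83633078 to 83633291, detected in 3.31% of MGT cells (2.98% to 3.67%) and 0.117% of LacZ cells (0.056% to 0.215%). Gata4, a zinc-finger factor on chromosome 14 at 63198914 to 63271712, had 6 such peaks of 19. The one at 63201507 to 63201651 was detected in 2.20% of MGT cells (1.93% to 2.49%) and 0.152% of LacZ cells (0.081% to 0.260%). Tbx5, a T-box factor on chromosome 5 at 119796514 to 119885220, had 8 of 12. Its peak at 119882937 to 119883532 was detected in 8.91% of MGT cells (8.38% to 9.47%) and 0.654% of LacZ cells (0.495% to 0.849%). Exons were not resolved here, so these peaks are placed within the genes and not in their exons or introns.

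**Figure D1:**
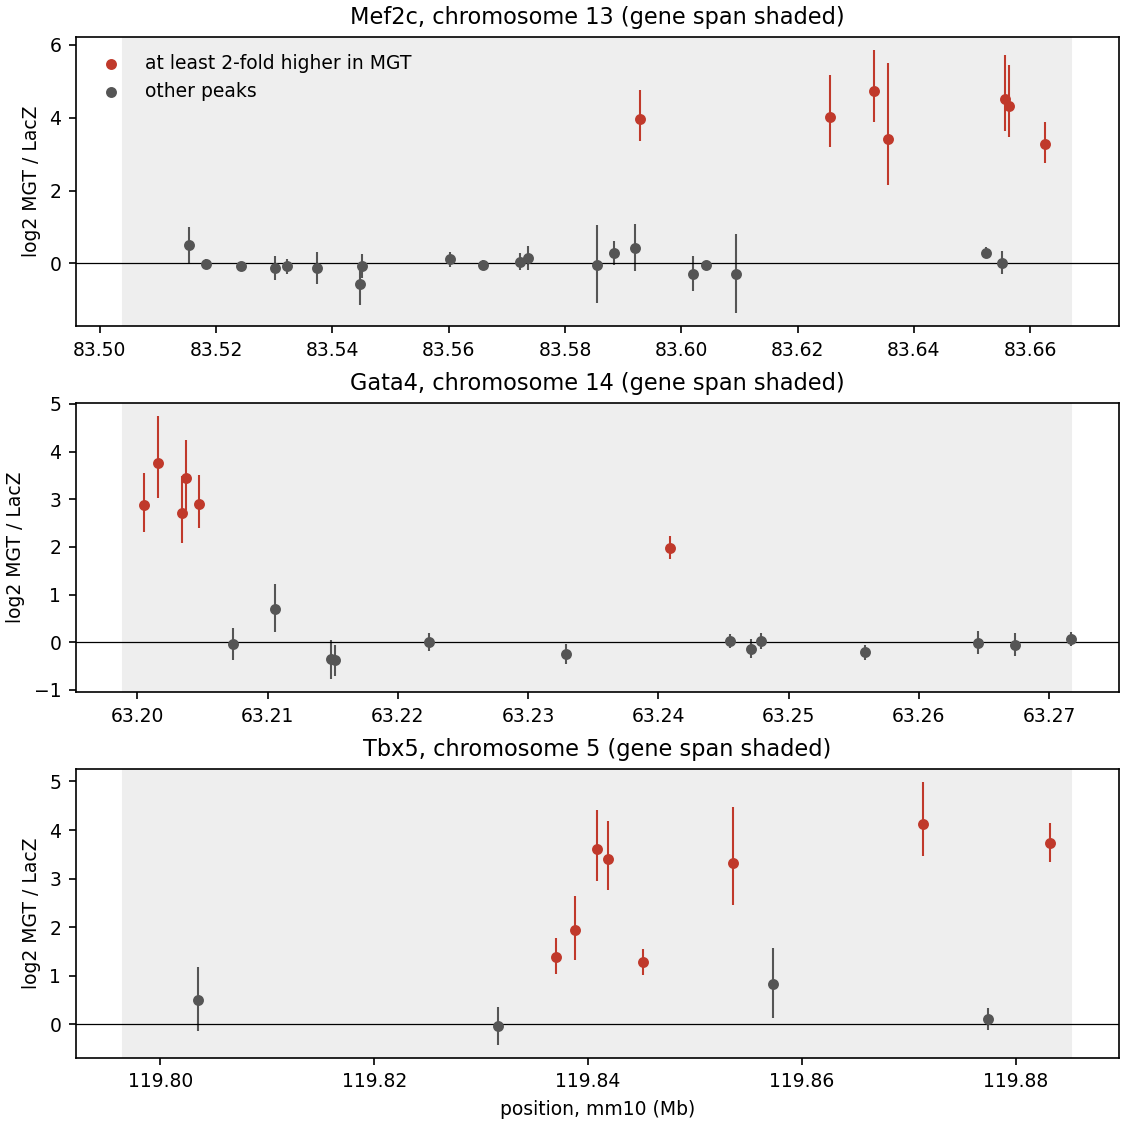
Log2 ratio of detections per 1000000, MGT over LacZ, for each peak within the spans of Mef2c, Gata4 and Tbx5 against its mm10 position in Mb; points are peaks and vertical lines 95% intervals from the numbers of cells, for counting error only. The 21 peaks in red are at least 2-fold higher in MGT, and the 37 in grey have a median log2 ratio of -0.03.

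The main comparison asked how accessibility differed across the genome between MGT and mock cells. Differences of at least 2-fold in the pooled cells were almost all toward higher accessibility in MGT and lay mostly away from gene ends. Most peaks differed little. Among 125836 peaks detected in at least 100 cells, 777 were at least 2-fold higher in MGT and 7 at least 2-fold lower. At 1.5-fold or more, 3506 were higher and 620 lower, and what counting error alone gives at that limit was not counted. Of the 777, 751 (96.6%) had no end of a protein-coding gene within 1 kb, against 85.7% of all measured peaks, and 20 lay within the spans of the delivered genes. These distal shares were not matched on detection. Peaks at gene ends were 13.1% of all peaks but held 29.8% of LacZ and 29.2% of MGT detections. The median log2 ratio was -0.01, and 96.7% of peaks lay within 1.5-fold. Across 100 simulated pairs with no difference but counting error, at most 8 peaks were at least 2-fold higher and at most 9 at least 2-fold lower. The 777 peaks were weakly detected, with medians of 39 LacZ and 128 MGT cells, and among peaks detected in at least 500 cells 20 were higher and 0 lower. Without the cells of 1 cluster made almost only of MGT cells, 68 peaks were at least 2-fold higher and 3 lower. The cluster was made partly from the same detections, so part of this fall may come from how its cells were picked. It held 20.9% of MGT cells, so a loss confined to it could not by itself lower a pooled ratio 2-fold, or even 1.5-fold.

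**Figure D2:**
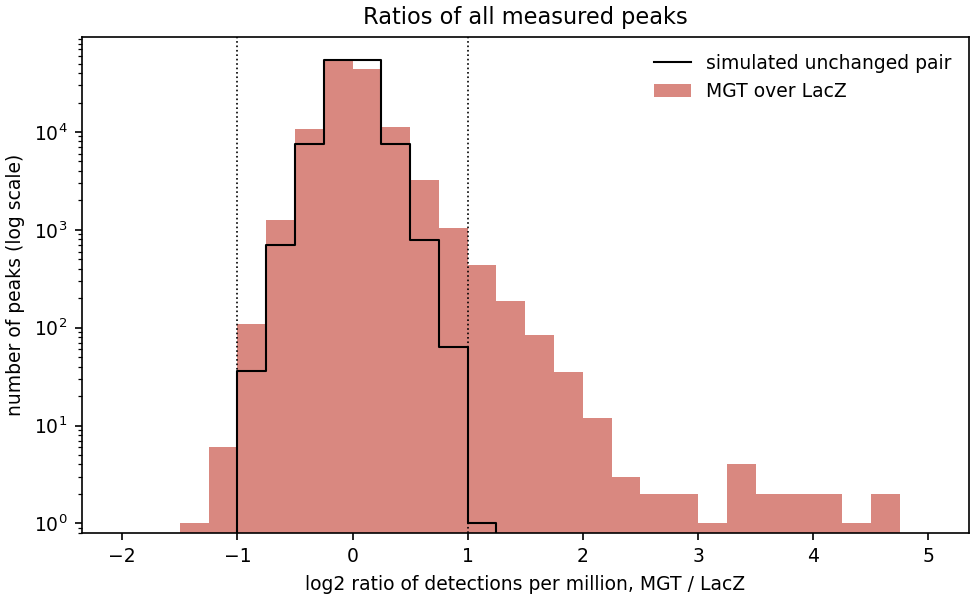
Number of measured peaks, on a log axis, by log2 ratio of detections per 1000000, MGT over LacZ; bars are the data, the black line is 1 simulated pair that differs by counting error only, and dotted lines mark 2-fold. The data reach above 2-fold for 777 peaks and below it for 7.

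Among distal peaks detected in at least 500 cells, the 5 with the highest ratios included 1 peak each within Tbx5 and Gata4. The next was on chromosome 2 at 102130975 to 102131594, within Ldlrad3, detected in 3.88% of MGT cells (3.53% to 4.27%) and 1.16% of LacZ cells (0.941% to 1.41%), a log2 ratio of 1.71. It was followed by a peak on chromosome 8 at 90013544 to 90014188, 233 kb from the nearest gene end, that of Tox3, with a log2 ratio of 1.47. The last was on chromosome 4 at 45037707 to 45038755, within Fbxo10, with a log2 ratio of 1.45. Without the cells of the cluster made almost only of MGT cells, these 3 log2 ratios were 0.80, 1.06 and 0.88. The cluster was made partly from these same peaks, so part of the fall may come from that. Picking peaks by their ratio overstates it at both ends. The most lost distal peaks moved less. Their log2 ratios ran from -0.56, on chromosome 3 at 127853301 to 127853703, 16.0 kb from an end of Ap1ar, to -0.50, on chromosome 10 at 127924867 to 127925420, 13.4 kb from an end of Sdr9c7. The others lay nearest to ends of Epb41l4a (-0.55), Ttc26 (-0.55) and Vcam1 (-0.53). Without the cells of the cluster made almost only of MGT cells, the lost peaks ran from -0.61 (near Ap1ar) to -0.31 (near Vcam1).

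Ratios were also summed over whole gene loci. Of the 10 protein-coding loci with the highest ratios, Krt31, which encodes a hair keratin, had the highest log2 ratio, 1.02. Csrp3, which encodes the muscle LIM protein of the Z-disc, had a log2 ratio of 0.88, with a peak detected in 5.68% of MGT cells (5.26% to 6.14%) and 3.07% of LacZ cells (2.72% to 3.46%). Lmod2 (0.84) and Lmod3 (0.68) encode leiomodins, which nucleate thin filaments. Smpx (0.86) encodes a small muscle protein, Trim72 (0.83) a membrane repair protein of muscle, and Abra (0.63) an actin-binding protein of muscle. The others were Gm45975 (0.87), Mlana (0.75) and Lsmem2 (0.62). The loci of Krt31, Gm45975, Lmod2, Trim72 and Lsmem2 each held only 1 peak. All 10 are also the top 10 loci of the cluster made almost only of MGT cells, and without its cells their log2 ratios ran from 0.26 (Mlana) to 0.54 (Krt31). That cluster was made partly from these same peaks, which favours such a match and such a fall. With clusters made from the other set of autosomes, the ratios outside the cluster ran from 0.28 (Abra) to 0.58 (Krt31). Smpx, on chromosome X, has no such value. The 10 highest and 10 lowest of 15325 loci were picked by their ratio, and the intervals do not allow for that. What counting error alone gives was not simulated for loci. The lowest locus was Vwde, with a log2 ratio of -0.46, detected in 2.65% of MGT cells (2.35% to 2.97%) and 3.50% of LacZ cells (3.13% to 3.92%). It was followed by Mmp27 (-0.39), the neighbours Gm8094 and Gm8104 (both -0.37, from the same detections), Tal1 (-0.36), Shfl (-0.33), Ceacam19 (-0.33), Alox12b (-0.32), Itgb7 (-0.32) and S100a14 (-0.31). Of 15325 loci with at least 500 detections, the delivered genes left out, 11 were at least 1.5-fold higher in MGT and 0 at least 1.5-fold lower, and without that cluster 0 were either. The loci of the delivered genes as a whole had log2 ratios of 1.74 for Tbx5, 0.30 for Mef2c and 0.28 for Gata4.

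Gene lists chosen before the data were examined differed by small amounts. Of 18 lists, 2 had a median above and 2 below the middle 95% of random lists matched on accessibility, where chance alone would put 0.90 of 18 outside. The other scalings (median-of-ratios, housekeeping end peaks, and shares of cells not scaled to depth, the last chosen after seeing the data) moved list medians by up to 0.03, so the size of a small median and the number of members above or below 0 depend on the scaling. The medians of 7 lists change sign with it: fibroblast identity, AP-1 and immediate early, inflammation and interferon, skeletal muscle, glycolysis, chromatin regulators and housekeeping. Sarcomere loci had a median log2 ratio of 0.07 (percentile 100 of 10000 random lists), with 18 of 25 measured members above 0. The highest were Csrp3 and Lmod2, and the lowest Myl2 (-0.22) and Myl3 (-0.13), the ventricular myosin light chains. Of the 180 measured peaks in these loci, 7 (3.89%) were at least 2-fold higher, against 0.618% of all measured peaks. Atrial and natriuretic loci had a median of 0.10 (percentile 99.8), with 10 of 11 above 0. The highest were Nppa (0.63), which encodes atrial natriuretic peptide, and Kcnj5 (0.55), a channel subunit of the atrial acetylcholine-gated potassium current, and the lowest Nr2f2 (-0.01) and Kcna5 (0.02). The Nppa value rests on 1 peak detected in 56 LacZ and 113 MGT cells. From loci without their end peaks, the atrial and natriuretic median was 0.06 and within the range of random lists (percentile 87.9). Without the cells of the cluster made almost only of MGT cells, both lists stayed above the range. The sarcomere median was then 0.04 (percentile 99.97) and the atrial and natriuretic median 0.05 (percentile 98.6).

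Other cardiac lists did not stand apart. The list of cardiac ion handling and conduction had a median log2 ratio of 0.01 (percentile 84.2). Its highest members were Ryr2 (0.28), the sarcoplasmic calcium release channel, and Fhod3 (0.22), which was listed there but encodes no channel or transporter. Atp2a2 (-0.11) was among the lowest. The list of endogenous cardiac transcription factors had a median of 0.00 (percentile 76.0). Smyd1 (0.22), listed there but a histone methyltransferase, and Esrrg (0.16) were highest, and Isl1 (-0.17) and Irx3 (-0.08) lowest. Oxidative metabolism had a median of 0.01 (percentile 91.7), from Ckmt2 (0.71), the sarcomeric mitochondrial creatine kinase, and Esrrg to Cd36 (-0.19) and Cox6a2 (-0.15). The Ckmt2 value rests on 1 peak detected in 37 LacZ and 79 MGT cells. Smooth muscle and myofibroblast loci had a median of 0.01 (percentile 90.9), from Des (0.31) and Myh11 (0.16) to Actg2 (-0.08) and Cnn1 (-0.06). Skeletal muscle had a median of -0.03 (percentile 38.0), from Des and Myh1 (0.28) to Tnni2 (-0.31) and Pax3 (-0.26).

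Fibroblast matrix loci were slightly lower in MGT, with a median log2 ratio of -0.06 (percentile 0.02) and 21 of 30 members below 0 (18 of 30 with housekeeping scaling or unscaled shares, where the median was -0.0250 or -0.0230). The lowest were Lum (-0.16) and Col3a1 (-0.13), and the highest Col6a2 (0.11) and Thbs1 (0.08). Without the cells of the cluster made almost only of MGT cells, this list had a median of -0.01 (percentile 51.0), and from loci without end peaks -0.02 (percentile 14.2). Cell cycle loci had a median of -0.06 (percentile 0.515), with 22 of 25 below 0 (17 with housekeeping scaling and 16 with unscaled shares, where the median was -0.0307 or -0.0287). Aurkb (-0.19) and Birc5 (-0.18), of the chromosomal passenger complex, were lowest, and Cdc20 (0.04) and Ccna2 (0.04) highest. The cell cycle list came within the range of random lists without the 5% shallowest and deepest barcodes (percentile 2.60), from loci without end peaks (percentile 17.4) and without the cluster made almost only of MGT cells (percentile 5.58). Fibroblast identity loci had a median of -0.03 (percentile 4.57), which unscaled shares turned to 0.0006, from Thy1 (0.18) and Tcf21 (0.05) to Fap (-0.21) and Meox2 (-0.13). No member of these 3 lists differed by 1.5-fold or more.

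The remaining lists lay within the range of random lists. TGF-beta signalling had a median log2 ratio of 0.01 (percentile 92.4), from Ltbp3 (0.11) and Smad4 (0.08) to Tgfbi (-0.12) and Tgfb3 (-0.09). AP-1 and immediate early loci had a median of -0.02 (percentile 41.9), from Klf6 (0.02) and Fosb (0.02) to Batf3 (-0.19) and Fosl1 (-0.18). Inflammation and interferon had a median of -0.01 (percentile 75.5), from Ifit1 (0.14) and C3 (0.12) to Cxcl5 (-0.27) and Cxcl1 (-0.20). Glycolysis had a median of -0.02 (percentile 35.5), from Pfkp (0.15) and Gpi1 (0.06) to Slc16a3 (-0.11) and Ldha (-0.08). Chromatin regulators had a median of -0.02 (percentile 45.1), from Tet1 (0.10) and Dnmt3b (0.07) to Bmi1 (-0.13) and Ring1 (-0.10). Neuronal loci had a median of -0.04 (percentile 13.2), from Snap25 (0.15) and Slc17a7 (0.06) to Elavl3 (-0.20) and Nefl (-0.19). Hepatic loci had a median of 0.00 (percentile 68.3), from Fga (0.21) and Apob (0.14) to Fgb (-0.61, on 85 LacZ and 72 MGT cells) and Foxa1 (-0.21). Housekeeping loci had a median of -0.02 (percentile 36.8), from Gusb (0.14) and Hprt (0.08) to Polr2a (-0.12) and Tbp (-0.09).

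**Figure D3:**
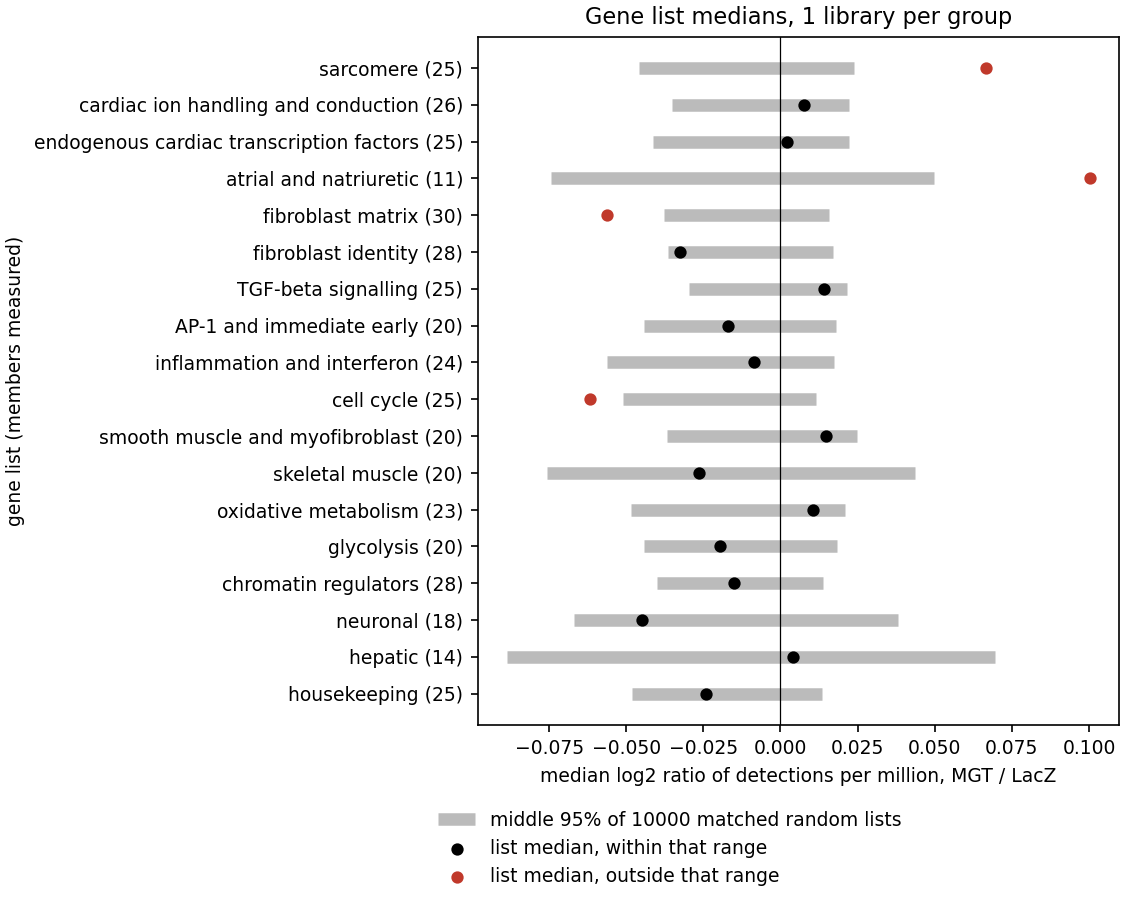
Median log2 ratio of detections per 1000000, MGT over LacZ, of each gene list (points), with the number of members measured; grey bars are the middle 95% of 10000 random lists matched on accessibility. The sarcomere (0.07) and the atrial and natriuretic (0.10) lists lie above their bars, and the fibroblast matrix (-0.06) and cell cycle (-0.06) lists below.

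The last comparison asked which kinds of cell each library held. Clustering of all cells without the delivered loci gave 7 clusters, of which 1 was named from the markers chosen before the data were examined. No limit for a name was set beforehand, and the named cluster had the highest median of any class in any cluster. In that cluster 6 of 7 epicardial or mesothelial markers were higher than in other cells, with a median log2 ratio of 1.16 and Upk3b, a mesothelial uroplakin, among its top 10 loci. These epicardial-like cells made up 4.98% of LacZ cells (4.53% to 5.46%) and 4.03% of MGT cells (3.67% to 4.42%). With the cluster made almost only of MGT cells left out of both totals, the shares were 4.99% (4.54% to 5.47%) and 5.10% (4.64% to 5.59%). No cluster was named from the fibroblast markers, which differed little between clusters, with medians from -0.13 to 0.08. In the cluster made almost only of MGT cells, 7 of 8 detected cardiomyocyte markers were higher than in other cells, with a median log2 ratio of 0.46 and none among its top 10 loci, but so were 7 of 8 macrophage markers (0.17) and 5 of 7 epicardial or mesothelial markers (0.29), and it was not named. Another cluster had the pericyte marker Abcc9 (1.16) among its top 10 loci and Kcnj8 at 0.84, both singled out after their values were seen, but the median of its 8 smooth muscle or pericyte markers was 0.09, with 5 higher, and it was not named either. Endothelial, lymphocyte and Schwann markers named no cluster either.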

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

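Alternatives that leave out cluster 4 (the cluster made almost only of MGT cells) or the peaks in the delivered spans, or that use shares of cells not scaled to depth, were chosen after seeing the data. The sarcomere list stood apart under all 12 alternatives run on lists (medians 0.04 to 0.10). Some of these could hardly have changed that. The other scalings shift the list and its random lists nearly alike, and the delivered genes are in no list. Causes of the changes below were not tested, except that other minimums and thinning change how many peaks are measured. Peaks at least 2-fold higher in MGT, 777 as reported, numbered 301 with cells thinned to 2000 detected peaks, 1380 with no minimum, 20 at 500 cells and 68 without cluster 4. Peaks at least 2-fold lower, 7 as reported, numbered 4 with scaling to housekeeping end peaks, 4 without the 5% shallowest and deepest barcodes, 4 without the epicardial-like cluster, 4 with unscaled shares, 144 with no minimum, 0 at 500 cells and 3 without cluster 4.

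List medians that left the tails of the random lists were cell cycle at -0.0526 without extreme depths, -0.0306 without end peaks and -0.0431 without cluster 4, atrial and natriuretic at 0.0554 without end peaks, and fibroblast matrix at -0.0175 without end peaks. Fibroblast matrix without cluster 4 (-0.0081) crossed to the other side of its random lists, at percentile 51.0. Medians that entered the tails were endogenous cardiac transcription factors (0.0352) and AP-1 and immediate early (-0.0586) with thinned cells, smooth muscle and myofibroblast (0.0284) on autosomes, cardiac ion handling and conduction (0.0157) from end peaks, and fibroblast identity (-0.0357) without end peaks. The summed gained peaks of Mef2c, Gata4 and Tbx5 (log2 4.03, 2.53 and 2.57) were rerun with median-of-ratios scaling and unscaled shares only, and stayed within their intervals.

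With clusters of thinned cells, epicardial-like cells were 3.53% of LacZ and 2.98% of MGT. Cluster 4 was not recovered there: the closest cluster shared 0.266 of their joint cells with it and held 15.1% of LacZ and 25.4% of MGT cells. Its share of MGT was 21.8% at the higher resolution, 22.4% without the 5% deepest barcodes and 18.7% with MGT clustered alone. Making values 0 or 1 changes nothing in these tables, 1 shared set of peaks leaves no overlap to choose, and motif alternatives were not run. Whether depth limits weak peaks more than strong ones was not tested; the median peak was detected in 1.54% of LacZ and 1.60% of MGT cells.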

Other observations

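The within-library contrasts, the split of cells and the counts of factors per cell were chosen after seeing the main results, as were all tests below except those on a difference that touches every cell and on the fibroblast markers. With 1 library per group, a cluster of almost only MGT cells may be that library and not a cell type, and cluster 4 is not recovered in thinned cells, where the closest cluster held 15.1% of LacZ cells.

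Within the MGT library alone, cells of the MGT-dominated cluster were compared with the other MGT cells, each locus being measured with clusters made from the other set of autosomes. Of the 18 lists, 4 lay above and 1 below the middle 95% of matched random lists, where chance would put 0.90 outside. Atrial and natriuretic loci had a median log2 ratio of 0.25 (percentile 99.99), sarcomere loci 0.12, oxidative metabolism 0.08 (percentile 99.2) and cardiac ion handling and conduction 0.06 (percentile 98.2), while fibroblast matrix loci had -0.08 (percentile 0.150). The sarcomere list was at percentile 99.97, where a difference touching every cell alike, as the whole cause, would leave it within their middle 95%. The highest of the loci named above were Trim72 (1.47), Lmod2 (1.45), Krt31 (1.42), Mlana (1.31) and Csrp3 (1.25). In MGT cells outside that cluster against LacZ cells outside it, sarcomere loci (0.04, percentile 99.9) and atrial and natriuretic loci (0.07, percentile 99.5) were again above and cell cycle loci below (-0.05, percentile 1.5), though with cluster 4 as made from all chromosomes left out cell cycle loci were within the range (-0.04, percentile 5.58). Whether the list medians inside and outside the cluster differ from each other was not tested.

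Peaks of more than 1 delivered factor were found together more often than independent detection gives. Of MGT cells, 11.1% (10.5% to 11.7%) had gained peaks of at least 2 factors, against 8.06% expected at matched depth, a ratio of 1.38 (1.31 to 1.45). In LacZ the share was 0.245% (0.152% to 0.375%). Cluster 2, whose cells were shallow (median 3021 detected peaks in MGT), had the highest share of MGT cells with a gained peak, 44.6% (42.7% to 46.4%). The share was 41.65% (36.98% to 46.43%) in the epicardial-like cluster and 41.3% (39.2% to 43.4%) in cluster 4.

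Far more peaks were at least 2-fold higher than lower in MGT. At 1.5-fold or more, 3506 peaks were higher and 620 lower. A loss confined to cluster 4, with 20.9% of MGT cells, could not by itself reach 2-fold or 1.5-fold. Neither count therefore shows that losses within it were fewer than gains. Depth is argued against as the whole cause. With every cell thinned to 2000 detected peaks, 301 of all 84803 peaks measured there were at least 2-fold higher and 8 lower. In 100 unchanged thinned pairs at most 10 were higher and 6 lower (569 of the 777 peaks had too few cells there). Delivered sequence is argued against as the whole cause for the 777 peaks, since 2.57% of them lay in the delivered spans. That share was not counted among the 20 higher peaks with at least 500 cells or the 68 left without cluster 4. The most gained distal peaks within Tbx5 and Gata4 kept log2 ratios of 3.65 and 1.97 without cluster 4. As the whole cause, a difference between the libraries that touches every cell alike is argued against by the contrast within MGT. There the 744 autosomal peaks outside the spans had a median log2 ratio of 1.51, against at most 0.09 in 1000 matched random sets of peaks. In other MGT cells over other LacZ cells the same peaks had a median log2 ratio of 0.76, so such a difference may still add to the excess. Picking peaks by their ratio overstates it: 1109 peaks picked in a random part of the cells had a median log2 ratio of 1.20 there, 0.83 in the remaining cells and 0.41 in the remaining cells without cluster 4. The 122 peaks picked as lower had a median log2 ratio of only -0.15 in the remaining cells, where 33.6% of them were above 0. A difference between the cultures or libraries that touched only some cells stays open, since each group is 1 library.

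Cluster 4 held 20.9% of MGT cells (20.2% to 21.7%) and 0.234% of LacZ cells (0.143% to 0.361%), and clusters from odd or even autosomes alone gave a cluster with 98.9% or 98.2% MGT cells. Doublets are argued against, since they would be deeper and the cluster's depth was 1.13 times that of other MGT cells. A library batch cannot be told apart from the factors, since each group is 1 library: 0 of the other 6 clusters had an MGT share outside 30% to 80%, a range set after the shares were seen, but a batch that touched only some cells would leave them there too. Cardiomyocytes carried over from the heart also stay open: against other MGT cells, cardiomyocyte marker loci had a median log2 ratio of 0.39 (from Nppa, 0.71, to Myl2, -0.04), and the -0.0515 of fibroblast marker loci excludes nothing, since these differed as little in the epicardial-like cluster (0.04), while the LacZ share argues only against equal carry-over in both cultures. The delivered factors as the cause cannot be told apart from none. Cells with a gained delivered peak were 1.06 times those expected at matched depth. The interval was 1.01 to 1.12 if binomial and 0.998 to 1.13 if Poisson, so the choice of interval decides it. Against MGT cells outside cluster 2, a reference chosen after that cluster's high share was seen, the ratio was 1.20 (1.14 to 1.26 and 1.12 to 1.28). Leaving the cluster with the highest share out of the reference raises the ratio by construction, so the 1.20 decides nothing.

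Short peaks in Mef2c, Gata4 and Tbx5 were gained in MGT. Opening of the native loci stays open: the other peaks of the 3 spans had a median log2 ratio of -0.0304 (0.31 for the 4 in Tbx5), but they were set apart by that same ratio, so their median excludes nothing. The gained peaks were found in MGT cells of every cluster, with a highest over lowest share of 1.40, which is consistent with fragments from the delivered retroviral sequence, whose coding exons map to these genes. Exon positions, which would test this directly, were not used here.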
